A study of Homo sapiens with 12 samples.

How the data were processed

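Transcript levels were measured by RNA sequencing in HCCC9810 and RBE, which are human cell lines of intrahepatic cholangiocarcinoma, a cancer of the bile ducts within the liver. Cells were grown with or without 5 µM anlotinib, an oral inhibitor of the VEGF, FGF and PDGF receptors and of KIT and RET, and were collected after 24 h. Per the labels, the drug was dissolved in dimethyl sulfoxide at a final 0.1%. Whether the control cultures received this solvent was not given in the sources used here. There were 12 libraries, 3 biological replicates for each of the 4 combinations of line and treatment, made from total RNA and read as pairs on an Illumina instrument.

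The deposited values were gene counts and RPKM (reads per kilobase of transcript, scaled to the counted reads of the library) for 58216 Ensembl genes. The authors' counts were whole numbers with no further scaling. The deposited RPKM values equalled the count divided by a fixed length per gene and by the column total, within 0.1%. The submitters' processing notes name HISAT2 as an aligner and GRCh38 as a genome build, and versions were not given in the sources used here. The counting program, its annotation, its strand setting and its handling of reads that fit several genes were also not given in the sources used here. All 58216 gene identifiers were present in GENCODE 29, which supplied coordinates (GRCh38), transcript lengths and GC content, and 56640 carried the same symbol there. Because the strand setting is unknown, reads of overlapping genes may have been counted for either gene, and the percentage of a named gene's exon bases shared with another gene is given where it exceeded 10%. Gene families with nearly identical members, among them metallothioneins, histones, hair keratins and chemokines of the CXCL1 group, are uncertain because the handling of reads that fit several genes is unknown.

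Columns were assigned to groups by the words in their headers, which name the line and control or treatment. The replicate numbers in the headers and those in the sample titles were in conflict: all 12 numbers belonged to titles of the other treatment in the same line. Libraries are named here by the number in the column header (HCCC9810 control 7 to 9, HCCC9810 anlotinib 10 to 12, RBE control 1 to 3, RBE anlotinib 4 to 6). No shared numbers tied treated to control libraries, so no pairing was used.

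Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's expression filter on the 4 groups, which left 18035 genes, and libraries were scaled by trimmed means of M values (TMM). A quasi-likelihood model with 4 group means was fitted to all 12 libraries, with robust estimation of the spread. Two-sided quasi-likelihood F-tests gave the effect of anlotinib in each line, the difference of the effects (RBE minus HCCC9810), their mean and the difference between the controls (RBE minus HCCC9810). P values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p below 0.05. Fold changes are log2 values ± SE from this model. The SE was derived from the test, as the log2 fold change before edgeR's shrinkage divided by the square root of F. Levels are counts scaled to the library size after normalization (CPM), given as mean ± SD with n = 3.

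Before the data were examined, 41 gene lists were fixed, covering the receptors anlotinib inhibits, signalling outputs, cell cycle, stress, metabolism and markers of cell types. Each was tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the 41 lists. The test was repeated with a correlation estimated for each list, and with fry, which asks whether the genes of a list move in one direction without comparing them with other genes. All lists had at least 5 tested members.

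The named genes were chosen by a rule set before the data were examined. In each line it took the 10 called genes with the largest rise and the 10 with the largest fall, with at least 5 CPM in the higher group and CPM ranges of treated and control libraries that did not overlap (3 against 3 libraries separate in this way by chance in 10% of genes). For the difference between lines it took the 10 genes with the smallest p, and for the controls the 5 largest differences in each direction. It added up to 4 members per direction from each list past the threshold, the receptors anlotinib inhibits, and CDKN1A, MKI67, KRT7 and KRT19. Genes on the sex chromosomes were not named. A group with no counts was set to 3 counts over its 3 libraries, and the resulting ratio is a lower bound that covers counting error only.

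The procedure was tested on simulated counts for 17723 genes with the depths and spread of these libraries. In HCCC9810 it recovered 22% of genes changed 1.5-fold, 68% of those changed 2-fold and 94% of those changed 4-fold, and 7.21% of 111 calls were false. In RBE the shares were 23%, 80% and 96%, with 6.72% of 119 calls false. For the difference between lines they were 3%, 49% and 83%, with 7.38% of 149 calls false. The list test called 0 of 40 unchanged lists and 5 of 5 raised lists. The simulated genes were drawn independently of each other. The simulation therefore does not show how often false calls arise, for lists above all, when genes vary together within groups. In each line 100 genes were changed 1.5-fold, 50 were changed 2-fold and 50 were changed 4-fold, all above a minimum mean count. In the real data 23.9% of genes were called in HCCC9810 and 17.7% in RBE. The recovered shares hold for few changed genes and may differ when many genes change or counts are low.

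Alternatives planned before the data were examined were DESeq2 1.42.0, other scalings (DESeq's ratio method, upper quartile, library totals), no low-count filter or a stricter one (a CPM above 1 and a mean count of 50), a fit of each comparison on its own 6 libraries, limma on log2 RPKM with an offset of 0.1 or 1, a 2-fold minimum, an adjusted p below 0.01, a fit without robust estimation, and leaving out each library in turn. Chosen after the data were seen were an offset per library for a smooth trend with GC content and transcript length, and a fit without the RBE anlotinib library 6 and the HCCC9810 control library 7. All 12 columns of each deposited table were used. Figures were drawn with matplotlib 3.10.9.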

Results

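RNA sequencing measured gene expression in the intrahepatic cholangiocarcinoma lines HCCC9810 and RBE after 24 h with or without 5 µM anlotinib, an inhibitor of several receptor tyrosine kinases. Each of the 4 groups held 3 libraries. Total counts ran from 16240478 to 22567927 in HCCC9810 control libraries, from 15215193 to 17722970 in HCCC9810 anlotinib libraries, from 17779598 to 31956474 in RBE control libraries and from 18227987 to 40963529 in RBE anlotinib libraries. Of 58216 genes in the table, 18035 had enough counts to be tested. All signs below rest on the words control and treatment in the column headers. If the replicate numbers in the sample titles were followed in their place, every effect of treatment would change sign and keep its size, counts up and down would trade places, and the comparison of untreated lines would be one of treated lines.

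The lines were far apart: the first principal component held 83.6% of the variance and separated HCCC9810 from RBE, and components 2 and 3 held 5.54% and 3.59%. Within groups, 62.5% of the variance over 9992 genes lay on one axis, whose gene loadings followed GC content (Spearman's rho 0.768 across genes, which are not independent replicates). RBE anlotinib library 6 and HCCC9810 control library 7 lay farthest out, at 24.0 and 21.5 on this axis. The log2 fold changes followed GC content in HCCC9810 (rho 0.431) more than in RBE (rho -0.0838), and after a correction per library for GC content and length the values were -0.0606 and 0.0135. For the difference of the effects rho was -0.408 and for their mean 0.289. After the correction these were 0.0559 and -0.036. Ribosomal RNA of the nucleus made up 1.57% of counts in HCCC9810 anlotinib library 11 and between 0.267% and 0.663% in the other libraries. Every pair of replicates differed by more than counting noise, with a chi-square per degree of freedom from 3.48 to 43.4.

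**Figure D1:**
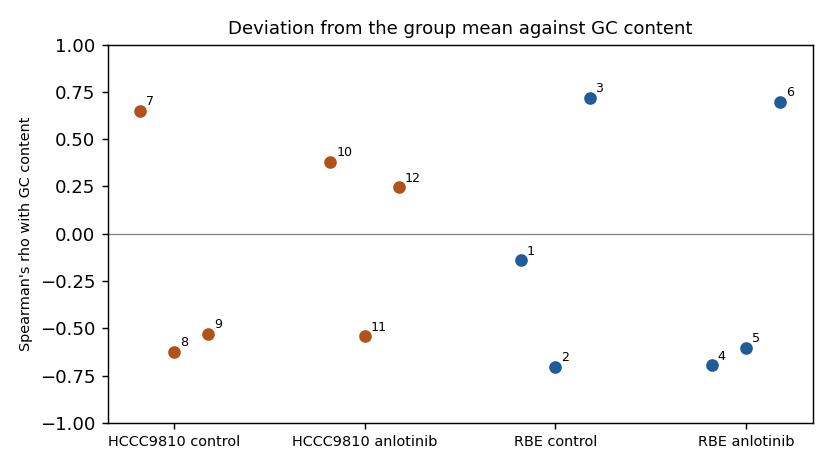
Spearman's rho (vertical axis, no unit) between GC content and the deviation of each library from its group's mean log2 CPM, 1 point per library, with the number of the column header beside it. Libraries 3, 6 and 7 lie at 0.719, 0.698 and 0.65, and library 2 lies at -0.704.

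The first comparison asked which transcripts anlotinib changed in HCCC9810. Of 25 genes of cholesterol synthesis 24 rose, among them INSIG1, which holds the sterol sensor of the SREBP pathway in the endoplasmic reticulum (29.4 ± 0.724 to 279 ± 17.1 CPM, log2 fold change 3.25 ± 0.12, adjusted p = 3.03e-10). SCD, the desaturase that makes monounsaturated fatty acids, rose from 197 ± 4.01 to 1802 ± 101 CPM (3.19 ± 0.11, adjusted p = 3.03e-10). The chemokine gene CXCL8 (2.36 ± 0.22) and the hypoxia-responsive NDRG1 (2.59 ± 0.22) also rose, while the TGF beta target PMEPA1 (-2.09 ± 0.14), the collagen gene COL5A1 (-1.22 ± 0.14) and the replication gene CDC6 (-0.99 ± 0.14) fell. Of the genes of mitosis, AURKA and the B cyclins rose and CDK1 and TOP2A fell. Values in brackets after gene symbols below are log2 fold changes ± SE.

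By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4303 of 18035 genes changed in HCCC9810 (23.9%), 1997 up and 2306 down, and of these 404 rose and 867 fell at least 2-fold. The excess of falls among all calls depended on the settings. With library totals as scaling, 1756 rose and 2671 fell. Rises made up 46.4% of calls in the main fit and 50.1% with DESeq2. They made up 49.6% with DESeq's ratio method and 49.2% in a fit of the 6 HCCC9810 libraries alone. The count was 2459 without control library 8 and 2407 without control library 9. The largest rises were those of ALDOC (4.08 ± 0.19), a brain-type aldolase of glycolysis (ENSG00000109107, chromosome 17, 28573115 to 28577264), MVD (3.26 ± 0.22), INSIG1 (ENSG00000186480, chromosome 7, 155297776 to 155310235), the homeobox gene PKNOX2 (3.21 ± 0.28), SCD (ENSG00000099194, chromosome 10, 100347124 to 100364834), CA9 (3.13 ± 0.23), DHCR7 (3.04 ± 0.16), FDFT1 (2.96 ± 0.18), the AP-1 subunit FOSB (2.81 ± 0.22) and LSS (2.72 ± 0.15). MVD, DHCR7, FDFT1 and LSS encode enzymes of cholesterol synthesis. The largest falls were those of the forkhead factor FOXS1 (-4.10 ± 0.48), keratin KRT4 (-3.84 ± 0.20, ENSG00000170477, chromosome 12, 52806549 to 52814551), the microtubule-associated MAP1B (-2.76 ± 0.16), FAM111B (-2.53 ± 0.36), the teneurin TENM2 (-2.42 ± 0.20), SAMD9 (-2.27 ± 0.44), cyclin E2 gene CCNE2 (-2.23 ± 0.22), endothelin EDN2 (-2.17 ± 0.26), the transcription factor MYB (-2.15 ± 0.27) and ZNF117 (-2.14 ± 0.49). Adjusted p values of these 20 genes lay between 3.03e-10 and 0.00901. The call for ZNF117 ended with log2(RPKM + 1), at adjusted p = 0.058. Exons overlapped those of another gene over 10.1% of ALDOC, 38.5% of CA9 and 37.1% of CCNE2.

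Lipid synthesis genes of HCCC9810 rose, most completely those of cholesterol synthesis. Of 25 genes of cholesterol synthesis, 24 rose and 0 fell (24 and 0 adjusted over the list alone), with a median log2 fold change of 2.11 (list test adjusted p = 8.18e-30, adjusted p = 0.03 with an estimated correlation). Among them were mevalonate kinase MVK (2.66 ± 0.14) and DHCR7, the last enzyme of the pathway to cholesterol. The fatty acid synthesis list had 12 of 21 genes up and 1 down (13 and 1 adjusted over the list alone), median 0.96 (list test adjusted p = 5.01e-09, adjusted p = 0.067 with an estimated correlation). These included fatty acid synthase FASN (2.10 ± 0.16), acetyl-CoA synthetase ACSS2 (1.76 ± 0.13) and the phosphatidate phosphatase LPIN1 (1.55 ± 0.12). Among lysosome genes, 14 of 40 rose and 1 fell (16 and 2 adjusted over the list alone), median 0.27 (list test adjusted p = 3.12e-05, adjusted p = 0.38 with an estimated correlation). Examples were the sialidase NEU1 (1.94 ± 0.14), the cholesterol exporter NPC1 (1.13 ± 0.11) and the lipase LIPA (0.67 ± 0.09). In the autophagy list 8 of 28 rose and 1 fell (9 and 1 adjusted over the list alone), median 0.13 (list test adjusted p = 0.00836, adjusted p = 0.359 with an estimated correlation). Among them were the cargo receptor SQSTM1 at 1.41 ± 0.13, the Rag GTPase gene RRAGD at 0.88 ± 0.12 and MAP1LC3B at 0.64 ± 0.10. Exon overlap was 22.0% for SQSTM1.

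In the signalling and stress lists given here, more genes of HCCC9810 rose than fell. NF-kB and cytokine genes rose in 16 of 23 cases and fell in 0 (18 and 0 adjusted over the list alone), median 1.17 (list test adjusted p = 2.07e-12, adjusted p = 0.0668 with an estimated correlation). These included the neutrophil chemokines CXCL8 (2.36 ± 0.22) and CXCL1 (2.33 ± 0.20) and the cytokines LIF (1.81 ± 0.16) and IL1B (1.81 ± 0.15). Of 20 genes that follow ERK signalling, 13 rose and 0 fell (14 and 2 adjusted over the list alone), median 0.81 (list test adjusted p = 6.14e-08, adjusted p = 0.178 with an estimated correlation). Examples were the early response factors EGR1 (2.20 ± 0.16) and FOS (1.60 ± 0.17) and the MAP kinase phosphatase DUSP5 (1.91 ± 0.16). Glycolysis and hypoxia genes rose in 20 of 34 cases and fell in 1 (23 and 2 adjusted over the list alone), median 0.50 (list test adjusted p = 1.31e-08, adjusted p = 0.178 with an estimated correlation). These included the hypoxia-responsive NDRG1 (2.59 ± 0.22) and BNIP3 (1.53 ± 0.17), while the kinase gene PFKFB3 fell (-0.63 ± 0.11). The ATF4 list had 17 of 37 genes up and 1 down (19 and 3 adjusted over the list alone), median 0.32 (list test adjusted p = 2.58e-05, adjusted p = 0.365 with an estimated correlation). Among them were the stress cytokine GDF15 (2.38 ± 0.19), the factor ATF3 (2.23 ± 0.20) and the pseudokinase TRIB3 (1.12 ± 0.14). Among p53 targets, 14 of 30 rose and 0 fell (17 and 0 adjusted over the list alone), median 0.40 (list test adjusted p = 6.23e-06, adjusted p = 0.178 with an estimated correlation). These included the growth arrest gene GADD45A at 1.19 ± 0.16 and FDXR at 0.95 ± 0.14. The cell cycle inhibitor CDKN1A stood at 0.44 ± 0.14 (adjusted p = 0.0285), a call that ended under limma on log2(RPKM + 0.1) with no filter (adjusted p = 0.115), the fits without control library 8 (0.124) or 9 (0.136), without anlotinib library 10 (0.116) or 11 (0.0648), and the GC and length correction (0.0703).

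Cell cycle genes of HCCC9810 moved in opposite directions. In the DNA replication and G1/S list 21 of 41 genes fell and 0 rose (0 up and 23 down adjusted over the list alone), median -0.47 (list test adjusted p = 3.09e-08, adjusted p = 0.38 with an estimated correlation). Examples were the origin licensing factor CDC6 (-0.99 ± 0.14), the polymerase subunit POLD3 (-1.08 ± 0.14), the primase PRIM1 (-1.44 ± 0.16, exon overlap 21.6%) and CCNE2. Of 46 genes of G2/M and mitosis, 20 rose and 5 fell (20 and 5 adjusted over the list alone), median 0.40 (list test adjusted p = 6.23e-06, adjusted p = 0.38 with an estimated correlation). The mitotic kinase AURKA (1.92 ± 0.15), the B cyclins CCNB1 (1.64 ± 0.16) and CCNB2 (1.60 ± 0.14) and securin PTTG1 (1.54 ± 0.14) rose. The kinase CDK1 (-1.54 ± 0.24), topoisomerase TOP2A (-1.58 ± 0.33), the kinetochore gene SPC25 (-0.70 ± 0.18) and the ubiquitin-conjugating UBE2C (-0.61 ± 0.14) fell. The proliferation marker MKI67 stood at -0.04 ± 0.15 (adjusted p = 0.879). Replication histones rose in 5 of 10 cases (6 and 1 adjusted over the list alone), median 0.49 (list test adjusted p = 0.00866, adjusted p = 0.359 with an estimated correlation), and after the GC and length correction the median was 0.47 and adjusted p = 0.101.

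More TGF beta targets and mesenchymal genes fell than rose in HCCC9810. Of 20 TGF beta targets, 16 fell and 1 rose (1 up and 17 down adjusted over the list alone), median -0.79 (list test adjusted p = 2.89e-07, adjusted p = 0.178 with an estimated correlation). Among them were the feedback regulator PMEPA1 (-2.09 ± 0.14) and collagen COL4A1 (-1.34 ± 0.14). The gene that rose was CTGF (1.02 ± 0.29), whose call ended without control library 8 (adjusted p = 0.0972) or 9 (0.0735), without anlotinib library 11 (0.0747) or 12 (0.0503), and in a fit of the 6 HCCC9810 libraries alone (0.0564). In the mesenchymal list 12 of 25 genes fell and 2 rose (4 up and 13 down adjusted over the list alone), median -0.60 (list test adjusted p = 0.00876, adjusted p = 0.178 with an estimated correlation). These included the collagens COL5A1 (-1.22 ± 0.14) and COL1A1 (-0.89 ± 0.14). Interferon response genes fell in 10 of 30 cases and rose in 3 (3 up and 15 down adjusted over the list alone), median -0.45 (list test adjusted p = 0.00836, adjusted p = 0.365 with an estimated correlation). The interferon-induced IFI44L (-3.34 ± 0.60) and IFI44 (-1.83 ± 0.27) fell, and the exonuclease ISG20 rose (1.35 ± 0.20). Counts of IFI44L were low, at 67 over the control libraries and 5 over the anlotinib libraries of HCCC9810. With the stricter low-count filter the adjusted p of the interferon list was 0.0565. The bile duct keratins KRT7 (-1.03 ± 0.19, adjusted p = 0.00138) and KRT19 (-0.89 ± 0.14, adjusted p = 0.000594) also fell.

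Several lists of HCCC9810 moved by smaller amounts. ER chaperones fell in 9 of 23 cases and rose in 1 (1 up and 11 down adjusted over the list alone), median -0.27 (list test adjusted p = 0.0256, adjusted p = 0.359 with an estimated correlation). Examples were the main luminal chaperones HSPA5 (-0.76 ± 0.10) and HSP90B1 (-0.94 ± 0.22). The WNT list had 4 of 10 genes down and none up (5 down adjusted over the list alone), median -0.44 (list test adjusted p = 0.0154, adjusted p = 0.178 with an estimated correlation). An example was TNFRSF19 at -1.34 ± 0.12. Drug metabolism and transport genes fell in 5 of 15 cases (0 and 5 adjusted over the list alone), median -0.49 (list test adjusted p = 0.00836, adjusted p = 0.178 with an estimated correlation). These included the efflux pump ABCB1 (-1.28 ± 0.18) and the aldehyde dehydrogenase ALDH1A1 (-1.35 ± 0.19). FOXO targets rose in 7 of 18 cases and fell in 1 (8 and 3 adjusted over the list alone), median 0.30 (list test adjusted p = 0.0168, adjusted p = 0.415 with an estimated correlation). An example was the insulin receptor substrate IRS2 at 0.86 ± 0.13. Without control library 7, which stood apart on the GC axis, adjusted p was 0.083 for ER chaperones, 0.0559 for WNT targets, 0.0698 for drug metabolism and 0.166 for FOXO targets (0.0515 with log2(RPKM + 1)), and ER chaperones stood at 0.0928 without anlotinib library 12.

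Growth genes of HCCC9810 shifted little. Ribosome biogenesis and MYC genes rose in 10 of 28 cases and fell in 2 (11 and 2 adjusted over the list alone), median 0.24 (list test adjusted p = 0.00836, adjusted p = 0.437 with an estimated correlation), with MYC itself at 0.93 ± 0.18. In the oxidative phosphorylation list 4 of 32 genes rose and 0 fell (2 and 0 adjusted over the list alone), median 0.12 (list test adjusted p = 0.0234, adjusted p = 0.594 with an estimated correlation). An example was the succinate dehydrogenase subunit SDHB at 0.51 ± 0.12. Of 13 mitochondrial transcripts, 2 were called, both up (none adjusted over the list alone), median 0.33 (list test adjusted p = 0.00282, adjusted p = 0.476 with an estimated correlation), and mitochondrial messenger RNA took 5.03 ± 0.612% of counts in control and 6.06 ± 0.428% in anlotinib libraries (n = 3 each). None of 50 ribosomal protein genes was called by edgeR or by DESeq2, 1 had an unadjusted p below 0.05, and the median was 0.19 (list test adjusted p = 0.00876, adjusted p = 0.689 with an estimated correlation). After the GC and length correction the median of the ribosomal protein list was 0.09 and adjusted p = 0.101. Without control library 9 adjusted p was 0.063 for ribosome biogenesis, 0.0641 for oxidative phosphorylation (0.0647 with the stricter filter) and 0.0776 for ribosomal proteins. By the rotation test of fry it was 0.206 for oxidative phosphorylation, 0.0554 for ribosome biogenesis, 0.0859 for mitochondrial transcripts and 0.369 for ribosomal proteins. Of the 41 lists, 23 were past the threshold in HCCC9810, and 1 of these, cholesterol synthesis, was past it with an estimated correlation.

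**Figure D2:**
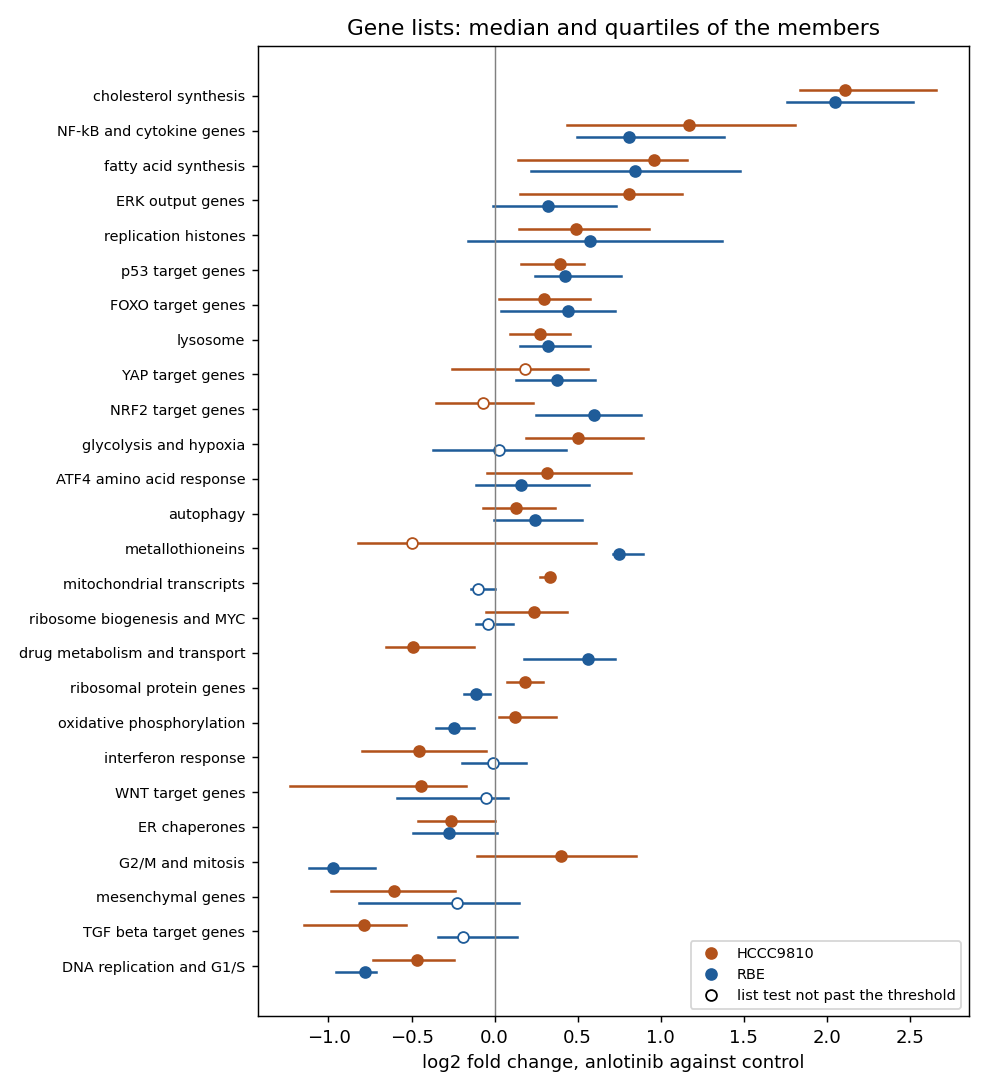
Median log2 fold change (points) and quartiles (lines) of the members of each gene list that passed the list test in HCCC9810 or RBE, anlotinib against control, with 3 libraries per group. Cholesterol synthesis had the highest median in both lines (2.11 and 2.05), and G2/M and mitosis stood at 0.40 in HCCC9810 and -0.98 in RBE.

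The same question was asked in RBE. Sterol genes rose here too, with HMGCS1, which makes the precursor of mevalonate, going from 41.4 ± 6.98 to 485 ± 46.6 CPM (log2 fold change 3.55 ± 0.21, adjusted p = 1.01e-07). The stress cytokine GDF15 rose from 37.3 ± 7.48 to 401 ± 72.7 CPM (3.42 ± 0.20, adjusted p = 7.81e-08) and the heme-degrading HMOX1 rose as well (2.37 ± 0.18, adjusted p = 5.42e-07). Of 41 genes of DNA replication 40 fell and of 46 of mitosis 38 fell (adjusted p = 0.157 and 0.132 with an estimated correlation). MKI67 fell from 588 ± 35.6 to 254 ± 26.9 CPM (-1.21 ± 0.15, adjusted p = 7.64e-05).

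By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3189 genes changed in RBE (17.7%), 1689 up and 1500 down, with 703 up and 230 down at least 2-fold. Which direction held more genes depended on the settings: with library totals 2050 rose and 1292 fell, and 2158 rose and 2495 fell without libraries 6 and 7. The count was 1868 without control library 1, 2114 without control library 3, 1941 without anlotinib library 4, 1884 without anlotinib library 5 and 4818 after the GC and length correction. The largest rises were those of the organic anion transporter SLCO4C1 (4.03 ± 0.25, ENSG00000173930, chromosome 5, 102233986 to 102296549), the muscle ring finger gene TRIM54 (3.59 ± 0.26), HMGCS1 (ENSG00000112972, chromosome 5, 43289395 to 43313512), ALDOC (3.46 ± 0.19), GDF15 (ENSG00000130513, chromosome 19, 18374731 to 18389176), hornerin HRNR (3.15 ± 0.23), the orphan nuclear receptor NR4A1 (3.02 ± 0.21), MVD (3.01 ± 0.21), the sterol methyl oxidase MSMO1 (2.96 ± 0.16) and ACSS2 (2.84 ± 0.13). The largest falls were those of the epithelial factor SPDEF (-1.95 ± 0.20), the proteoglycan SPOCK1 (-1.86 ± 0.11), the helicase PIF1 (-1.86 ± 0.19, ENSG00000140451, chromosome 15, 64815632 to 64825668), keratin KRT81 (-1.83 ± 0.24), the long non-coding RNA NKILA (-1.71 ± 0.14), the receptor NTRK3 (-1.69 ± 0.16), the kinetochore pair SPC24 (-1.68 ± 0.16) and SPC25 (-1.65 ± 0.19), OLFM4 (-1.62 ± 0.22) and CDCA3 (-1.60 ± 0.18). Adjusted p values of these 20 genes lay between 1.42e-08 and 0.000235. Exon overlap was 10.1% for ALDOC, 15% for HMGCS1, 10.3% for NR4A1 and 13.2% for NKILA, a transcript antisense to another gene while the strand of the reads was not given in the sources used here. Reads of KRT81 could also stem from its near-identical paralogs.

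More lipid synthesis and lysosome genes rose than fell in RBE. Cholesterol synthesis had 24 of 25 genes up and 0 down (24 and 0 adjusted over the list alone), median 2.05 (list test adjusted p = 2.05e-33, adjusted p = 0.0207 with an estimated correlation). These included INSIG1 (2.59 ± 0.11) and the sterol reductase TM7SF2 (2.04 ± 0.11). Of 21 fatty acid synthesis genes, 13 rose and 0 fell (13 and 2 adjusted over the list alone), median 0.84 (list test adjusted p = 5.85e-09, adjusted p = 0.107 with an estimated correlation). Examples were SCD (2.00 ± 0.11) and the acyl-CoA synthetase ACSL1 (1.62 ± 0.10). Lysosome genes rose in 14 of 40 cases and fell in 1 (18 and 1 adjusted over the list alone), median 0.32 (list test adjusted p = 2.84e-07, adjusted p = 0.302 with an estimated correlation). Among them were NEU1 (1.98 ± 0.14) and LIPA (1.31 ± 0.09) up and the protease CTSB down (-0.82 ± 0.13). The autophagy list had 9 of 28 genes up and 0 down (10 and 0 adjusted over the list alone), median 0.24 (list test adjusted p = 0.000239, adjusted p = 0.186 with an estimated correlation). These included RRAGD (1.54 ± 0.12) and the receptor OPTN (1.07 ± 0.12). NRF2 targets rose in 16 of 25 cases and fell in 1 (16 and 2 adjusted over the list alone), median 0.60 (list test adjusted p = 1.09e-07, adjusted p = 0.157 with an estimated correlation). Examples were HMOX1 and thioredoxin reductase TXNRD1 (1.27 ± 0.11). Drug metabolism and transport genes rose in 7 of 15 cases and fell in 1 (9 and 2 adjusted over the list alone), median 0.56 (list test adjusted p = 0.00185, adjusted p = 0.157 with an estimated correlation). Among them were the efflux pumps ABCB1 (0.84 ± 0.16) and ABCC2 (0.61 ± 0.12).

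Both arms of the cell cycle fell in RBE. In the G2/M and mitosis list 38 of 46 genes fell and 0 rose (40 down adjusted over the list alone), median -0.98 (list test adjusted p = 3.44e-26, adjusted p = 0.132 with an estimated correlation). These included SPC25, the phosphatase CDC25C (-1.52 ± 0.17), UBE2C (-1.51 ± 0.15) and the passenger protein gene INCENP (-1.28 ± 0.13). Of 41 genes of DNA replication and G1/S, 40 fell and 0 rose (41 down adjusted over the list alone), median -0.78 (list test adjusted p = 7.47e-26, adjusted p = 0.157 with an estimated correlation). Examples were the ribonucleotide reductase subunits RRM2 (-1.28 ± 0.13, exon overlap 20.2%) and RRM1 (-0.94 ± 0.11). Among p53 targets 14 of 30 rose and 0 fell (16 and 0 adjusted over the list alone), median 0.42 (list test adjusted p = 1.22e-07, adjusted p = 0.157 with an estimated correlation). Among them were GADD45A (1.29 ± 0.16), CDKN1A (1.04 ± 0.14) and the pro-apoptotic BBC3 (0.89 ± 0.14). FOXO targets rose in 9 of 18 cases and fell in 0 (10 and 0 adjusted over the list alone), median 0.44 (list test adjusted p = 0.000203, adjusted p = 0.29 with an estimated correlation). These included PIK3IP1, an inhibitor of PI3K (1.48 ± 0.19), and the ubiquitin ligase FBXO32 (1.39 ± 0.12).

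More inflammatory and early response genes rose than fell in RBE. The NF-kB and cytokine list had 16 of 23 genes up and 0 down (16 and 1 adjusted over the list alone), median 0.81 (list test adjusted p = 1.91e-08, adjusted p = 0.132 with an estimated correlation). Examples were CXCL8 (1.92 ± 0.23), the monocyte chemokine CCL2 (1.78 ± 0.24) and CSF1 (1.47 ± 0.13). YAP targets rose in 10 of 21 cases and fell in 2 (11 and 2 adjusted over the list alone), median 0.38 (list test adjusted p = 0.00188, adjusted p = 0.401 with an estimated correlation). Among them were ANKRD1 (2.36 ± 0.26) and CTGF (1.93 ± 0.25). ERK output genes rose in 9 of 20 cases and fell in 2 (11 and 2 adjusted over the list alone), median 0.32 (list test adjusted p = 0.00399, adjusted p = 0.401 with an estimated correlation). DUSP5 (1.64 ± 0.16) and EGR1 (1.23 ± 0.16) rose, while the pathway's feedback inhibitor SPRY4 (-0.75 ± 0.10) and the factor ETV5 (-0.54 ± 0.10) fell. ER chaperones fell in 8 of 23 cases and rose in 1 (4 up and 10 down adjusted over the list alone), median -0.28 (list test adjusted p = 0.00479, adjusted p = 0.202 with an estimated correlation). These included the disulfide isomerase PDIA4 at -0.73 ± 0.10 and HSPA5 at -0.49 ± 0.10.

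Stress, histone, metal and ribosome genes of RBE moved in lists whose calls changed with the libraries or the test used. The ATF4 list had 10 of 37 genes up and 4 down (11 and 4 adjusted over the list alone), median 0.16 (list test adjusted p = 0.0179, adjusted p = 0.55 with an estimated correlation). Genes called were ATF3 (2.39 ± 0.20) and TRIB3 (2.12 ± 0.14) up and the serine synthesis gene PSAT1 down (-0.59 ± 0.10). Its adjusted p was 0.155 without control library 2 and 0.188 without anlotinib library 6. Replication histones rose in 5 of 10 cases and fell in 2 (5 and 2 adjusted over the list alone), median 0.57 (list test adjusted p = 0.028, adjusted p = 0.401 with an estimated correlation). Its adjusted p was 0.0933 without anlotinib library 6 and 0.0569 without HCCC9810 control library 7. Of 5 metallothionein list genes, 2 rose and 0 fell (3 and 0 adjusted over the list alone), median 0.75 (list test adjusted p = 0.028, adjusted p = 0.186 with an estimated correlation). MT1F (1.91 ± 0.37) and the zinc exporter SLC30A1 (0.90 ± 0.17) rose. Its adjusted p was 0.0522 without control library 2, 0.131 without anlotinib library 6 and 0.119 with no low-count filter (0.199 by limma). In the oxidative phosphorylation list 1 of 32 genes rose and 2 fell (none adjusted over the list alone), median -0.24 (list test adjusted p = 0.000361, adjusted p = 0.417 with an estimated correlation, 0.0647 by fry). None of the 50 ribosomal protein genes was called by edgeR or DESeq2, 2 had an unadjusted p below 0.05, and the median was -0.11 (list test adjusted p = 0.0188, adjusted p = 0.818 with an estimated correlation). That list's adjusted p was 0.157, 0.139 and 0.749 without control library 3, anlotinib library 4 and anlotinib library 5, 0.155 after the GC and length correction (median -0.03), 0.0811 with the stricter filter and 0.499 by fry, and its median was 0.03 without anlotinib library 5. Of the 41 lists, 19 were past the threshold in RBE, and 1 of these, cholesterol synthesis, was past it with an estimated correlation.

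Among the receptors that anlotinib inhibits, calls were made in RBE. In HCCC9810 none of the 7 tested receptor genes was called by edgeR or DESeq2, and 2 had an unadjusted p below 0.05 (list median -0.08, test in the upward direction, adjusted p = 0.761). In RBE the FGF receptor gene FGFR2 (1.22 ± 0.20, adjusted p = 0.000669) and PDGFRB (0.80 ± 0.21, adjusted p = 0.0158) rose, and RET (-1.81 ± 0.35, adjusted p = 0.00218) and PDGFRA (-0.72 ± 0.20, adjusted p = 0.0219) fell (list adjusted p = 0.804). The call for PDGFRB ended without control library 1 (adjusted p = 0.0859) and by limma with no filter (0.132). That for PDGFRA, with an exon overlap of 15.8%, ended with library totals (0.053), by limma with no filter (0.109) and without control library 1 (0.0589), control library 2 (0.0859) or anlotinib library 4 (0.0698). FGFR1 stood at -0.08 in HCCC9810 and -0.23 in RBE, FGFR3 at -0.34 and -0.04, and FGFR4 at 0.39 and -0.20, none of them called. Without libraries 6 and 7, FGFR1 (log2 fold change -0.34, adjusted p = 0.0391) and FGFR4 (-0.31, 0.0361) were called in RBE and FGFR4 in HCCC9810 (0.48, 0.028). FGFR3 was called in HCCC9810 with library totals (-0.42, adjusted p = 0.0408), by limma on log2(RPKM + 0.1) (-0.42, 0.04) or log2(RPKM + 1) (-0.34, 0.0453), and after the GC and length correction (-0.55, 0.0012). In HCCC9810, RET and PDGFRA each had 4 counts over the 3 control libraries and 2 over the 3 anlotinib libraries. The VEGF receptor genes KDR, FLT1 and FLT4 and the receptor gene KIT had too few counts to be tested in these lines. In RBE the duct keratin KRT19 rose (0.54 ± 0.14, adjusted p = 0.0161) and KRT7 stood at -0.14 ± 0.18 (adjusted p = 0.658). The call for KRT19 ended without control library 1 (adjusted p = 0.0727), control library 2 (0.0859) or anlotinib library 6 (0.053).

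Lists of angiogenic, apoptotic, junction and cell type genes were not past the threshold of camera in either line or for the difference. By fry, adjusted p in HCCC9810 was 0.000678 for endothelial markers, 0.00191 for angiogenic ligands, 0.0082 for fibroblast markers and for epithelial junction genes and 0.00941 for PI3K, AKT and mTOR components. In RBE it was 0.0123 for epithelial junction genes, 0.0125 for apoptosis regulators and 0.0184 for matrix proteases and inhibitors. For the difference it was 0.00338 for endothelial markers, 0.00361 for epithelial junction genes, 0.0389 for matrix proteases and inhibitors, 0.0126 for PI3K, AKT and mTOR components and 0.0343 for angiogenic ligands. Counts in HCCC9810 and then RBE, with the adjusted p of the list test in brackets, were for angiogenic ligands 6 up and 4 down of 16 (0.283) and 5 and 3 (0.804), for other receptor tyrosine kinases 4 up and 5 down of 19 (0.829) and 2 and 2 (0.743), for PI3K, AKT and mTOR components 5 up and 1 down of 21 (0.235) and 1 and 1 (0.347), and for CDK inhibitors and D cyclins 2 up and 1 down of 9 (0.75) and 2 and 1 (0.76). They were for apoptosis regulators 8 up and 4 down of 33 (0.159) and 6 and 1 (0.178), for epithelial junction genes 3 up and 6 down of 22 (0.347) and 3 and 0 (0.0834), for matrix proteases and inhibitors 1 up and 4 down of 16 (0.692) and 4 and 1 (0.222), and for antigen presentation 1 up and 1 down of 20 (0.287) and 1 and 0 (0.431). For the stress and lineage lists they were for heat shock genes 4 up and 1 down of 16 (0.206) and 2 and 1 (0.804), for cholangiocyte markers 2 up and 7 down of 20 (0.248) and 2 and 4 (0.844), for hepatocyte markers 1 up and 1 down of 16 (0.235) and 0 and 1 (0.567), and for fibroblast markers 0 up and 4 down of 8 (0.0649) and 1 and 1 (0.455). They also covered other cell types, for endothelial markers 0 up and 3 down of 5 (0.148) and 1 and 1 (0.431), and for immune cell markers 2 up and 1 down of 5 (0.732) and 1 and 0 (0.431). The median and mean differed in sign for immune cell markers (0.35 and -0.15) and CDK inhibitors and D cyclins (0.01 and -0.03) in HCCC9810, and for cholangiocyte markers in RBE (0.11 and -0.08). The lists past the threshold of camera in HCCC9810 and not in RBE stood in RBE at adjusted p = 0.911 for glycolysis and hypoxia (8 genes up and 8 down of 34), 0.205 for TGF beta targets (2 up and 3 down of 20), 0.205 for mesenchymal genes (3 up and 5 down of 25), 0.791 for interferon response (3 up and 3 down of 30, median -0.01 and mean 0.00), 0.222 for WNT targets (1 up and 2 down of 10, 0.0183 by fry), 0.711 for ribosome biogenesis and MYC (2 up and 3 down of 28) and 0.322 for mitochondrial transcripts (none of 13 by edgeR or DESeq2, nor at an unadjusted p below 0.05). Those past it in RBE and not in HCCC9810 stood in HCCC9810 at 0.96 for NRF2 targets (5 up and 5 down of 25), 0.172 for YAP targets (6 up and 3 down of 21) and 0.75 for metallothioneins (1 down of 5). The test of the difference itself gave adjusted p = 0.314 for mesenchymal genes, 0.259 for WNT targets, 0.303 for YAP targets and 0.139 for metallothioneins, and 0.0267, 0.0162, 0.194 and 0.0101 by fry.

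**Figure D3:**
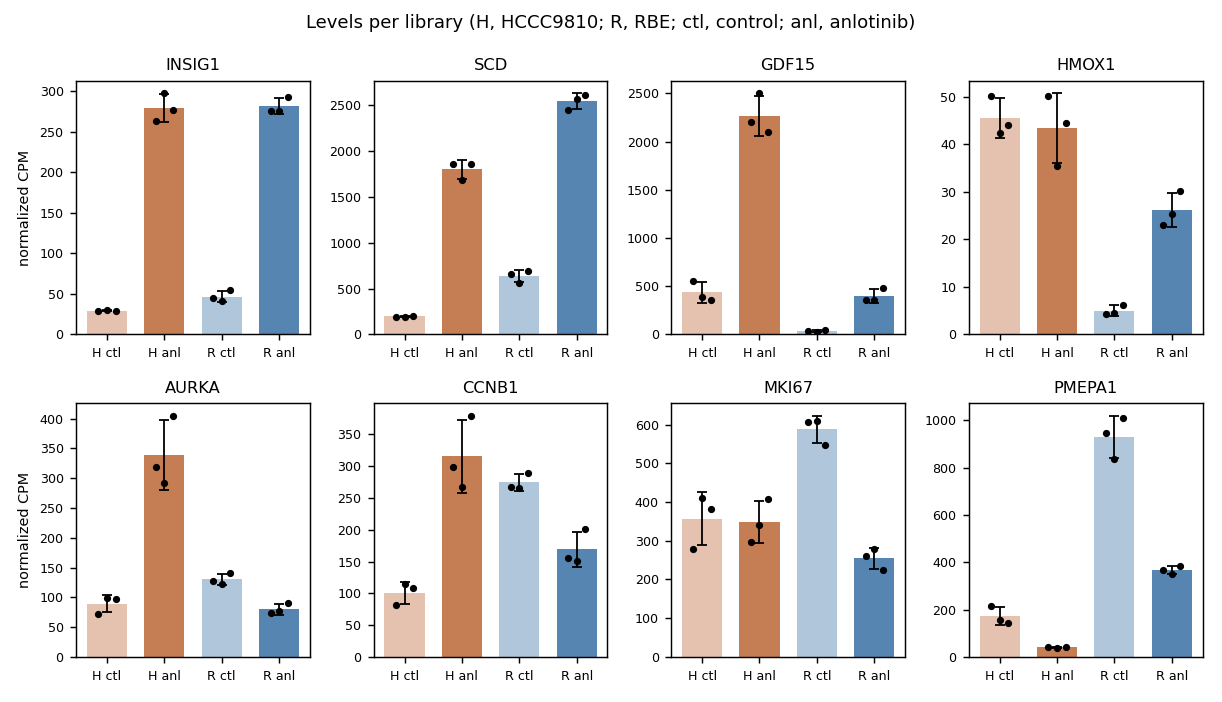
Normalized CPM (vertical axes, from 0) of 8 genes in the 12 libraries, with bars for the means, error bars for SD and points for the 3 libraries of each group. INSIG1 and SCD rose in both lines, AURKA and CCNB1 rose in HCCC9810 and fell in RBE, and HMOX1 rose in RBE.

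The design also allowed a test of whether the lines responded differently. Of 46 genes of G2/M and mitosis, 20 rose in HCCC9810 and fell in RBE, and 5 fell in both. KIF20A, a kinesin of cytokinesis, rose by 1.61 in HCCC9810 and had a log2 fold change of -1.29 in RBE, a difference of -2.89 ± 0.23 (adjusted p = 7.88e-06). AURKA went from 1.92 in HCCC9810 to -0.71 in RBE (difference -2.62 ± 0.21, adjusted p = 7.88e-06). Keratin KRT4 showed the reverse, at -3.84 in HCCC9810 and 2.86 in RBE (difference 6.70 ± 0.39, adjusted p = 2.6e-07), from 169 ± 50.3 CPM in HCCC9810 controls and 0.212 ± 0.0585 CPM in RBE controls. The efflux pump gene ABCB1 responded higher in RBE (2.12 ± 0.24, adjusted p = 7.82e-05) and the glycolytic LDHA lower (-1.24 ± 0.17, adjusted p = 0.000323).

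By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2990 genes responded differently (16.6%), 1608 higher and 1382 lower in RBE. With library totals alone as scaling, the median of all genes lay at 0.219 in place of 0.0898 and 65.7% of calls were higher, against 53.8%. The share of calls that were higher was 50.8% with DESeq2 and 49.5% without libraries 6 and 7. Which direction held more calls thus depended on the settings. Without the libraries 6 and 7 that stood apart, the count was 6413 and 96.2% of the 2990 genes were still called. The share still called was 84.6% after the GC and length correction and 83% by limma on log2(RPKM + 0.1). By limma on log2(RPKM + 0.1) with no filter the count was 1771. Leaving out 1 library gave 1784 (RBE control 1), 1641 (RBE control 3), 1565 (RBE anlotinib 4), 1473 (RBE anlotinib 5), 4865 (RBE anlotinib 6), 1727 (HCCC9810 control 8) and 1681 (HCCC9810 control 9). The other genes with the smallest p were the glycosyltransferase GCNT4 (3.57 ± 0.30), MAP1B (3.48 ± 0.20) and the immune receptor gene SLAMF7 (3.15 ± 0.25), all down in HCCC9810 and up in RBE. CCNB2 (-2.32 ± 0.19), TROAP (-2.48 ± 0.19), PIMREG (-2.60 ± 0.21) and PIF1 (-3.33 ± 0.29) were up in HCCC9810 and down in RBE.

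Of 46 G2/M and mitosis genes, 32 responded lower and 0 higher in RBE (36 lower adjusted over the list alone), median difference -1.40 (list test adjusted p = 1.47e-25, adjusted p = 0.272 with an estimated correlation), and 20 of them both rose in HCCC9810 and fell in RBE. Among DNA replication and G1/S genes, 8 of 41 responded lower and 2 higher (2 and 11 adjusted over the list alone, higher and lower), median -0.37 (list test adjusted p = 0.000794, adjusted p = 0.713 with an estimated correlation), and 20 fell in both lines. NRF2 targets responded higher in 13 of 25 cases and lower in 1 (13 and 1 adjusted over the list alone), median 0.83 (list test adjusted p = 0.000511, adjusted p = 0.469 with an estimated correlation). An example was HMOX1 at -0.07 (adjusted p = 0.778) in HCCC9810 and 2.37 in RBE. Without libraries 6 and 7 the adjusted p of this list was 0.0517. Drug metabolism and transport genes responded higher in 7 of 15 cases (7 and 0 adjusted over the list alone), median 0.61 (list test adjusted p = 0.000175, adjusted p = 0.272 with an estimated correlation). An example was ABCB1 down in HCCC9810 and up in RBE (difference 2.12 ± 0.24). TGF beta targets responded higher in 9 of 20 cases (13 and 0 adjusted over the list alone), median 0.72 (list test adjusted p = 0.000511, adjusted p = 0.469 with an estimated correlation). An example was COL4A1 at a difference of 1.37 ± 0.19.

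Glycolysis and hypoxia genes responded lower in RBE in 15 of 34 cases and higher in 2 (4 and 18 adjusted over the list alone, higher and lower), median -0.55 (list test adjusted p = 9.71e-06, adjusted p = 0.469 with an estimated correlation). These included the lactate dehydrogenase LDHA (-1.24 ± 0.17) and the mutase PGAM1 (-1.25 ± 0.18). In the ERK output list 7 of 20 responded lower and 2 higher (2 and 8 adjusted over the list alone, higher and lower), median -0.41 (list test adjusted p = 0.00453, adjusted p = 0.53 with an estimated correlation). Examples were ETV5 (-1.33 ± 0.15) and FOSL1 (-1.49 ± 0.22). NF-kB and cytokine genes responded lower in 5 of 23 cases and higher in 2 (2 and 9 adjusted over the list alone, higher and lower), median -0.57 (list test adjusted p = 0.0106, adjusted p = 0.53 with an estimated correlation). Among them were IL1B (-1.28 ± 0.30) lower and CCL2 (1.49 ± 0.33) higher. The oxidative phosphorylation list had 6 of 32 genes lower and none higher (10 lower and 1 higher adjusted over the list alone), median -0.47 (list test adjusted p = 5.59e-05, adjusted p = 0.53 with an estimated correlation). Ribosome biogenesis and MYC had 3 of 28 lower (1 adjusted over the list alone), median -0.22 (list test adjusted p = 0.0206, adjusted p = 0.677 with an estimated correlation), with adjusted p = 0.115 without HCCC9810 control library 9 or anlotinib library 11. None of 13 mitochondrial transcripts (median -0.38, list test adjusted p = 0.00208, adjusted p = 0.677 with an estimated correlation) and none of 50 ribosomal protein genes (median -0.27, list test adjusted p = 0.000361, adjusted p = 0.713 with an estimated correlation) was called by edgeR or DESeq2, while 5 and 2 had an unadjusted p below 0.05. After the GC and length correction the adjusted p of both the MYC list (median -0.09) and the mitochondrial list (median -0.17) was 0.0688. For cholesterol synthesis 4 genes responded higher and 4 lower (4 and 8 adjusted over the list alone), with a median of -0.26, a mean of 0.02 and adjusted p = 0.248. Interferon response genes had 7 higher and 1 lower of 30, with adjusted p = 0.081 by camera and 0.0468 by fry. For the lists not past the threshold adjusted p lay between 0.081 and 0.919. By fry it was 0.253 for DNA replication, 0.0613 for NF-kB, 0.171 for MYC, 0.152 for mitochondrial and 0.287 for ribosomal protein genes. No list was past the threshold with an estimated correlation.

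**Figure D4:**
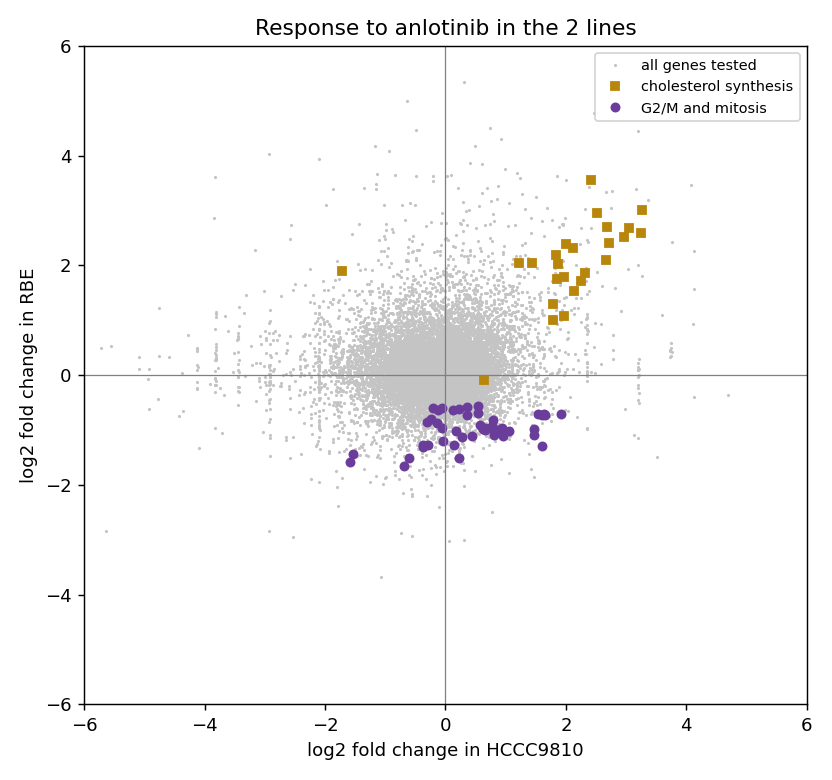
Log2 fold change in RBE (vertical axis) against that in HCCC9810 (horizontal axis), 1 point per gene for the 18035 tested genes, with cholesterol synthesis and G2/M and mitosis genes marked. Sterol genes lie mostly up in both lines, and mitotic genes lie mostly below 0 in RBE and on either side of 0 in HCCC9810.

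Shared changes were then counted. Of the genes called in each line, 477 rose in both against 187 for independent lists, and 318 fell in both against 191.8. Another 190 rose in HCCC9810 and fell in RBE (166.1 for independent lists), and 162 fell in HCCC9810 and rose in RBE (216). Of the 795 genes that moved the same way, 81 also differed in size between the lines. The same-direction count was 505 without RBE control library 1 and 1318 after the GC and length correction. Shared rises took in 23 of 25 cholesterol synthesis genes, 12 of 23 NF-kB and cytokine genes, 8 of 40 lysosome genes and 6 of 30 p53 targets. Across all 18035 genes, most of them not called, the fold changes of the lines were weakly related (Pearson's r 0.097, Spearman's rho 0.0283, genes not being independent replicates). Over the 6345 genes called in either line Pearson's r was 0.182.

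Averaged over both lines, 3763 genes changed by edgeR's quasi-likelihood test, 1913 up and 1850 down. INSIG1 (2.92 ± 0.08), SCD (2.60 ± 0.08), ALDOC (3.77 ± 0.13), GDF15 (2.90 ± 0.14) and CXCL8 (2.14 ± 0.16) were among the genes with the clearest average rise within their lists, and PMEPA1 (-1.71 ± 0.10), COL5A1 (-1.22 ± 0.10) and HSPA5 (-0.63 ± 0.07) were among those that fell. Of 41 lists, 20 were past the threshold for the average, and 3 remained so with an estimated correlation: cholesterol synthesis (adjusted p = 0.0135), NF-kB and cytokine genes (0.0311) and fatty acid synthesis (0.0311). The average for interferon response (adjusted p = 0.0429) lost its call without RBE control library 2 (0.0612), HCCC9810 control library 9 (0.0564), anlotinib library 11 (0.0941) or 12 (0.0844), and with the stricter filter (0.233).

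The untreated lines themselves differed widely. HCCC9810 controls held H19, an imprinted non-coding RNA, at 9930 times the RBE level (95% counting interval 8020 to 12500) and the secreted isomerase AGR2 at 5230 times (3120 to 9560). The cadherin gene CDH11 was higher in HCCC9810 at 3760 times (1610 to 11600, from 5 counts in RBE). SERPINB2 was at least 2060-fold and the trefoil factor TFF2 at least 1110-fold higher in HCCC9810, with no counts in RBE controls. RBE controls held PPP2R2C, a phosphatase subunit gene, at least 696-fold higher, WDR72 at least 345-fold, LHFPL4 at least 236-fold and ZNF718 at least 223-fold higher, with no counts in HCCC9810 controls. By edgeR's quasi-likelihood test 11558 genes differed (64.1%), 5676 higher and 5882 lower in RBE. Line and any difference in culture or library batch could not be separated.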

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

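The corrections for GC content and length, the fit without libraries 6 and 7 and the test of the numbers in the column headers were chosen after the data had been seen. Single far values within groups were not tested, because each group held 3 libraries.

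The mitotic genes AURKA and KIF20A and the keratin gene KRT4 responded differently to anlotinib in the 2 lines. By the interaction test of edgeR, 2990 genes differed in their response. For single genes the difference of the log2 fold changes, RBE minus HCCC9810, was 6.70 for KRT4, 3.57 for GCNT4, 3.48 for MAP1B and 3.15 for SLAMF7. It was -2.32 for CCNB2, -2.48 for TROAP, -2.60 for PIMREG, -2.62 for AURKA, -2.89 for KIF20A and -3.33 for PIF1. The median difference was -1.40 for G2/M and mitosis, -0.55 for glycolysis and hypoxia, -0.57 for NF-kB and cytokine genes, -0.47 for oxidative phosphorylation, -0.41 for ERK output genes, -0.38 for mitochondrial transcripts, -0.37 for DNA replication and G1/S, -0.27 for ribosomal protein genes and -0.22 for ribosome biogenesis and MYC. It was 0.83 for NRF2 targets, 0.72 for TGF beta targets and 0.61 for drug metabolism and transport. With an estimated correlation none of these lists was past the threshold (adjusted p from 0.272 to 0.713).

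Of 46 genes of G2/M and mitosis, 20 rose in HCCC9810 and fell in RBE, 5 fell in both, and the list difference had adjusted p = 0.272 with an estimated correlation. After the correction for GC content and length the median difference was -1.53. Over the fits that each left out 1 library it ran from -1.48 to -1.25. These values argue against a GC or length trend or a single library as the whole cause. Relative to the median of all genes the list difference was -1.49 at its nearest to 0 under 3 other scalings. A scaling moves all genes of a library alike, so this value was fixed in advance and cannot test the scaling. Under those scalings the median of all genes lay between 0.0589 and 0.219, against 0.0898 in the main fit. These shifts were small beside the list's -1.40. A biological difference between the lines stays open as untested.

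In HCCC9810, 16 of 20 TGF beta targets fell and 1 rose, and 10 of 30 interferon response genes fell and 3 rose (adjusted p = 0.178 and 0.365 with an estimated correlation). For TGF beta targets the median was -0.863 after the GC and length correction, and over the fits that each left out 1 library it ran from -0.811 to -0.647. For interferon response genes it was -0.449 after the correction and ran from -0.56 to -0.353, with a highest adjusted p of 0.0335. These values argue against the GC trend and against a single library as the whole cause, although the stricter filter ended the interferon call (median -0.271, adjusted p = 0.0565). A response of the cells stays open as untested.

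The numbers in all 12 column headers belonged to sample titles of the other treatment. The words control and treatment in the headers were followed. Whether the words or the numbers were right cannot be told apart, because the tables hold no untreated reference from outside the series. An exchange would change the sign of every effect of anlotinib and keep its size, counts up and down would trade places, and the comparison of untreated lines would be one of treated lines.

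Other splits of the libraries were counted. For HCCC9810, RBE and the untreated lines, 10 splits of 6 libraries were too few for a share under 0.05, and 1 split in each case, the real one, gave as many genes: 4303, 3189 and 11558, with 0 in the highest other split. For the difference of response, 2 of 100 splits gave at least the real 2990 genes, and the other split, with 3763 genes, was the real one with the labels of 1 line mirrored. Such splits ask whether treatment had any effect, so they do not decide whether the lines responded alike. For the average over the lines, 2 of 100 splits gave at least the real 3763 genes. The other, with 3810 genes, kept the real HCCC9810 groups and set RBE libraries 1, 3 and 6 against 2, 4 and 5, which follows the GC axis. So many genes were thus reached without the RBE treatment labels, and the splits do not decide whether the average reflects both lines. After the GC and length correction the average had 5150 genes. For genes that moved the same way in both lines, 1 of 100 splits, the real one, reached 795 genes, and the highest other, 352, was again the mirrored one. This count adds nothing to the splits within each line, where the other splits gave 0 genes.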

How the results depend on the processing

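The GC and length correction and the fit without libraries 6 and 7 were chosen after the data had been seen. No paired analysis was possible because the replicate numbers did not link control and anlotinib libraries. No result changed direction past the threshold. Of 400 results for named genes, 389 kept their side of the threshold after the GC and length correction, 395 without libraries 6 and 7, 398 with DESeq2, 392 with library totals and 357 by limma on log2(RPKM + 0.1) with no filter. Over the fits that each left out 1 library, a call ended in 302 of 4800 cases. Most named genes were picked for their calls in these same data, so this stability is partly built in. Over all called genes, the GC and length correction kept 83.6% in HCCC9810, 95.8% in RBE and 84.6% for the difference. Of 74 list results, 69 kept their call after the correction, 66 without libraries 6 and 7, 62 by fry and 5 with an estimated correlation. A 2-fold minimum left 1271 genes in HCCC9810, 933 in RBE, 1437 for the difference, 568 for the average, 6403 between controls and 168 in the same direction. An adjusted p below 0.01 left 2008, 1679, 1031, 2008 and 370 for HCCC9810, RBE, the difference, the average and the same direction, since both thresholds admit fewer genes. The GC and length correction gave 4818 genes in RBE and 1318 in the same direction. Without libraries 6 and 7 the difference had 6413 genes, and by limma on log2(RPKM + 0.1) with no filter 1771. With an estimated correlation 1 list was past the threshold in HCCC9810 (against 23), 1 in RBE (19), 0 for the difference (12) and 3 for the average (20). For these changes the cause was not tested. Leaving out each library in turn gave 2407 to 5043 genes in HCCC9810, 1868 to 3750 in RBE, 1473 to 4865 for the difference, 2666 to 3962 for the average, 10747 to 12278 between controls and 505 to 804 in the same direction, and 20 to 24, 17 to 19, 11 to 13 and 19 to 22 lists for HCCC9810, RBE, the difference and the average. Low counts left KDR, FLT1, FLT4 and KIT without a test.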

Other observations

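The list tests between untreated lines were chosen after the data had been seen. Interferon and antigen presentation genes were lower in RBE than in HCCC9810 before any treatment. Of 30 interferon response genes, 24 were lower and 0 higher in RBE (adjusted p = 3.86e-06, adjusted p = 0.453 with an estimated correlation), and of 20 antigen presentation genes 18 were lower and 0 higher (3.86e-06 and 0.453). ER chaperones were lower in RBE in 17 of 23 cases and higher in 1 (0.00122 and 0.453), lysosome genes lower in 26 of 40 and higher in 2 (0.00123 and 0.684), NF-kB and cytokine genes lower in 17 of 23 and higher in 4 (0.0033 and 0.669), and replication histones lower in 6 of 10 (0.0149 and 0.669). Higher in RBE were 28 of 50 ribosomal protein genes, with 4 lower (0.00431 and 0.727), 6 of 7 tested anlotinib target receptors, with 1 lower (0.0149 and 0.599), 9 of 16 hepatocyte markers (0.0189 and 0.684) and 23 of 46 G2/M and mitosis genes, with 5 lower (0.0414 and 0.727). Among these receptors RET and PDGFRA had 4 counts each over the HCCC9810 controls, and PDGFRB had 6, 4 and 7. They passed the expression filter through their counts in RBE. Of 41 lists, 10 were past the threshold and 0 with an estimated correlation. Line and batch could not be separated in these values.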
